A study of Mus musculus with 6 samples.

How the data were processed

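Total RNA from 6 cultures of primary mouse keratinocytes was measured on 6 Agilent one-colour whole-genome arrays, 3 from PBS-treated and 3 from Anakinra-treated cultures. Groups were taken from the treatment label of each sample and replicate numbers from the sample titles. Per the labels' protocols, total RNA was converted to cDNA and then to labelled cRNA, and the label was Alexa-555. Per the file headers, each array was scanned in 1 channel and read with Agilent Feature Extraction 9.5.3.1, which the submitters' processing notes also name.

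The deposited scanner files hold 1 intensity per spot. Per the file headers and column names, the authors' processed intensity was background-subtracted and detrended within each array, very dim spots were replaced by a surrogate value, and nothing was normalised between arrays. The scanner files also hold the mean spot and local background intensity and the flags for outlier, saturated and dim spots. The authors' deposited value table is on a log2 scale. Each of its columns equalled the log2 of the processed intensity of the same array plus 1 constant, to within 0.001, and the constants brought every array to nearly the same linear mean, between 3314.26 and 3314.31. Its column medians were 5.77, 5.83 and 6.22 in PBS and 5.74, 7.00 and 6.21 in Anakinra. Scale and direction are therefore known, while the rule behind the constants is not given in the sources used here. The values in the table are not centred per gene.

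The analysis started from the log2 of the processed intensity minus the 75th percentile of the same array. Control spots and spots with an outlier flag were left out, spots of 1 probe were averaged, and a probe entered if it was well above background on all arrays of at least 1 group and had at least 2 values per group. Where several probes of a gene passed, the one with the highest mean signal stood for the gene. Of 43379 non-control spots, 41174 different probes covered 27573 gene names. Names were updated through a table of RefSeq genes of assembly GRCm38.p6. A RefSeq accession named 23374 probes, a current symbol 6733 and a synonym held by 1 gene 2919, while 8148 probes kept the name in the file. Probe positions are those of the array design, on mouse build mm8. Of 6080 tested genes with several passing probes, none had called probes going both ways. Among 83 called genes with several probes, 4 had a probe of the opposite sign (Rdh9, Cx3cl1, Tfcp2l1 and Mbnl3).

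Anakinra was compared with PBS by a linear model per gene in limma 3.58.1 under R 4.3.3, with lmFit and eBayes, a two-sided test and Benjamini-Hochberg adjustment over the 16494 genes tested; an adjusted p under 0.05 counts as past the threshold. Log2 changes are Anakinra minus PBS, given with their standard error (SE), and a fold is 2 to the power of the size of that change. Shifts of 19 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. Lists needed at least 5 tested genes. These list tests used genes with a value on every array; 90 tested genes lacked one, none of them in a list. The test design, the lists and the alternatives were fixed before the data were examined. So was the rule for named genes, which took the 10 largest rises and 10 largest falls among called genes with a symbol that were above background on all arrays and whose groups did not overlap. It also took 7 genes of the targeted pathway, 17 genes of prior interest, and from each list up to 4 called members with the smallest p, or 2 members where none was called. A gene this rule took, which did not pass, is not reported here. A last part, for called genes not above background on any array of 1 group, named no gene. Genes in the lists' descriptions outside this rule were chosen after their values were seen.

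Data were simulated from each gene's mean and limma's estimate of its spread, in 20 runs with 200 of 16494 genes changed. That estimate is drawn towards a value common to all genes. The limma fit recovered 61.9% of genes changed by 1 and 83.2% of those changed by 2 on the log2 scale. False genes made up 5.50% of the calls, and 0 of the 20 random lists had a p under 0.05. Genes were simulated independently and with the same spread on every array. These rates therefore do not cover correlated genes, arrays of unequal quality, or genes whose spreads differ more than those estimates. The weights that limma estimated for the real arrays were 1.27, 3.09 and 2.08 for PBS 1, 2 and 3. For Anakinra 1, 2 and 3 they were 0.978, 0.353 and 0.355, each below every PBS array. Pairs of arrays correlated at 0.995 to 0.997 within PBS and at 0.957 to 0.983 within Anakinra. The main fit assumed the same spread in both groups.

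The number of arrays, 3 per group, limits the precision. The labels do not say whether replicates came from separate animals or isolations, so the p-values measure only the spread between these cultures, which may be technical. Alternatives covered background correction by normexp with an offset of 50, quantile, median and cyclic loess scaling, the authors' value table, the background filter, outlier spots, the handling of several probes, the variance model, array weights, the slide and the replicate number as blocks, stricter thresholds, and leaving out each sample. Cyclic loess and a run on the brighter part of the genes were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No genome sequence of build mm8 was used here, so positions within exons are not given.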

Results

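The samples were primary keratinocytes, the main cell type of the epidermis, isolated from newborn wild-type mice and transduced with the v-ras-Ha oncogene by a virus given at 10 particles per cell. At 5 hours after transduction 3 cultures received Anakinra, a recombinant form of the interleukin-1 (IL-1) receptor antagonist, at 5 ug/ml and 3 received PBS. RNA was taken after 3 more days, with the antagonist replaced after 2 days. The comparison asks which genes in ras-expressing keratinocytes depend on signalling through the IL-1 receptor, in particular those of the NF-kB pathway. The 75th percentile of the processed signal was 864, 987 and 1006 on the PBS arrays and 1002, 1087 and 1065 on the Anakinra arrays. Probes well above background made up 66.9%, 62.5% and 71.0% of each PBS array, and 56.1%, 86.5% and 55.6% of Anakinra arrays 1, 2 and 3. No spot was saturated.

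Among genes above background on all arrays, inflammatory chemokines fell most under Anakinra, and markers of the differentiating upper epidermis rose. Cxcl5, which attracts neutrophils, was 33.3-fold lower, with a log2 change of -5.06 ± 0.25 (SE, n = 3 per group, limma adjusted p = 0.00326; -4.22 with normexp background correction). Ccl20, which attracts dendritic and T cells, was 11.0-fold lower at -3.46 ± 0.08 (adjusted p = 0.000525), and the monocyte chemokine Ccl2 was 9.18-fold lower at -3.20 ± 0.24 (adjusted p = 0.00854). Keratins 10 and 1, which replace the basal keratins when keratinocytes leave the basal layer, were 5.27-fold and 5.10-fold higher, at 2.40 ± 0.26 for Krt10 (adjusted p = 0.0206) and 2.35 ± 0.19 for Krt1 (adjusted p = 0.0112), though with the slide as a block neither passed (adjusted p = 0.0938 and 0.0599). Of 16494 genes tested, 160 were higher and 132 lower in Anakinra, and 2653 had an unadjusted p under 0.05. With per-array medians in place of the 75th percentile, 8 were higher and 49 lower.

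The other large falls among genes above background on all arrays were in C3 at -3.18 ± 0.08, the central complement component, Cxcl1 at -3.12 ± 0.12, Cxcl3 at -2.69 ± 0.09, Tnf at -2.63 ± 0.11, Csf2 at -2.34 ± 0.13, the cholesterol 25-hydroxylase Ch25h at -2.15 ± 0.06 and the kinase gene Ankk1 at -2.03 ± 0.06. Large rises were measured for Aadacl2fm1 at 2.62 ± 0.16, the threonine dehydrogenase Tdh at 2.54 ± 0.27, the calmodulin-like gene Calm5 at 2.53 ± 0.17, the protease inhibitor gene Spink8 at 2.30 ± 0.31, the gasdermin Gsdmc at 2.04 ± 0.14, the acyl-CoA thioesterase Them5 at 2.03 ± 0.18, the carboxypeptidase Cpn1 at 1.98 ± 0.20 and the serpin Serpinb7 at 1.92 ± 0.08. All of these had adjusted p-values of 0.0376 or less. The size of the changes in dim genes depends on the background correction: with normexp, Aadacl2fm1 was at 1.19, Spink8 at 0.95 and Cpn1 at 0.89, while Krt10 was at 2.41. Like Krt10 and Krt1, Tdh, Spink8, Them5 and Cpn1 did not pass with the slide as a block (adjusted p from 0.0503 for Cpn1 to 0.140 for Spink8). Among the called genes, 65 higher and 59 lower ones changed at least 2-fold. In all 292 the 3 values of one group lay beyond those of the other. Passing the threshold with so few values leaves little room for overlap, so this follows from the selection. Groups were separated in this way in 26.2% of the tested genes. Chance gives 10% for a single gene, but genes vary together across arrays, so the difference is not a test.

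**Figure D1:**
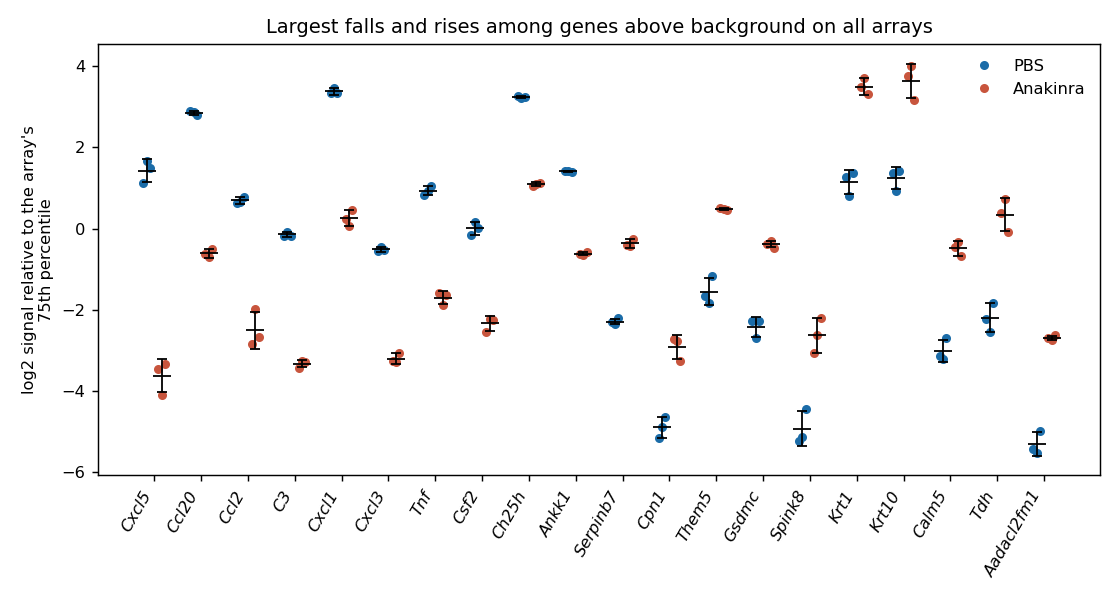
Signal of the 10 genes with the largest falls (left, from Cxcl5 to Ankk1) and the 10 with the largest rises (right, from Serpinb7 to Aadacl2fm1) among called genes that were above background on all arrays and whose groups did not overlap, as log2 relative to each array's 75th percentile; points are arrays, 3 per group, and bars give the mean and SD. Cxcl5 has a mean of 1.43 in PBS and -3.62 in Anakinra.

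In the targeted pathway, the agonist itself fell. Il1a, which encodes IL-1 alpha, was 2.85-fold lower at -1.51 ± 0.09 (n = 3 per group, limma adjusted p = 0.00391). Il18 rose at 1.33 ± 0.13 (adjusted p = 0.0161), as did Il1f8, the IL-36 beta gene, at 0.78 ± 0.07 (adjusted p = 0.0130). Of the 23 tested members of the IL-1 family and receptor list, 2 rose, 1 fell and 20 did not pass; adjusted over the list alone the counts were 4 and 3. The receptor gene Il1r1 was at 0.25 ± 0.18 (adjusted p = 0.576), the decoy receptor Il1r2 at 0.46 ± 0.26 (adjusted p = 0.456), the accessory protein Il1rap at 0.10 ± 0.21 (adjusted p = 0.881) and the natural antagonist Il1rn at -0.36 ± 0.10 (adjusted p = 0.166). Il1b was at -0.14 ± 0.70 (adjusted p = 0.963) and above background on 1 of the 3 Anakinra arrays. The host Hras gene was at -0.05 ± 0.11 (adjusted p = 0.886); whether its probe also binds the viral transcript is not known here. The list as a whole had a median of 0.10 (camera adjusted p = 0.179). Il1a was not past the threshold without PBS 1 (adjusted p = 0.0562) or without PBS 2 (adjusted p = 0.0631), with changes of -1.52 and -1.47. With the slide as a block it passed, while Il18 (adjusted p = 0.0759) and Il1f8 (adjusted p = 0.0647) did not.

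Secreted cytokines and chemokines fell as a group. Of 24 tested members 15 fell, 2 rose and 7 did not pass, with a list median of -1.62 (camera adjusted p = 6.61e-15; 0.0114 with an estimated correlation); adjusted over the list alone, 18 fell and 4 rose. Besides those above, the macrophage growth factor Csf1 fell at -1.66 ± 0.06, the neutrophil growth factor Csf3 at -3.30 ± 0.24 and Cxcl2 at -3.51 ± 0.38; the last pair was above background on only 2 of the 3 Anakinra arrays, and with normexp background correction Csf3 was at -2.20 and Cxcl2 at -1.86. In a fit with the slide as a block 11 fell and 1 rose, and neither Csf3 (adjusted p = 0.0503) nor Cxcl2 (adjusted p = 0.0927) passed. The 2 that rose were Tslp, an epithelial cytokine of allergic inflammation, at 0.83 ± 0.06, and Il11 at 0.77 ± 0.10. Il6 was not above background on any array and was not tested. The array design places Cxcl5, Cxcl3, Cxcl1 and Cxcl2 in 1 cluster on chromosome 5 of mm8, with the Cxcl5 probe at 91836379 to 91836438 and the Cxcl2 probe at 91980708 to 91980767.

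NF-kB feedback and target genes shifted down. Of 23 tested, 6 fell, 0 rose and 17 did not pass, and adjusted over the list alone 14 fell; the list median was -0.47 (camera adjusted p = 7.08e-13; 0.0114 with an estimated correlation). Tnfaip2 fell at -1.50 ± 0.07, the kinase Ikbke at -1.30 ± 0.07, Nfkbia, which encodes the inhibitor IkB alpha, at -1.23 ± 0.08, and the adhesion molecule Icam1 at -0.73 ± 0.07. Of the 23, 3 fell with the slide as a block, where Icam1 did not pass (adjusted p = 0.0759). Tnfaip3, which encodes the feedback inhibitor A20, was at -0.66 ± 0.15 (adjusted p = 0.112), and the cyclooxygenase gene Ptgs2 at 0.20 ± 0.13 (adjusted p = 0.529).

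Acute-phase and antimicrobial genes were lower in part. Of 16 tested, 5 fell, 1 rose and 10 did not pass, and adjusted over the list alone 9 fell and 1 rose. C3 fell as given above, the protease inhibitor Slpi fell at -1.89 ± 0.11, and Lcn2, an iron-sequestering protein, fell at -4.75 ± 0.35 while it was above background on 1 of the 3 Anakinra arrays (-2.91 with normexp background correction). The beta-defensin gene Defb1 rose at 1.04 ± 0.06. Saa3 and Steap4, which fell only when adjusted over the list alone, were above background on 1 and 2 of the 3 Anakinra arrays. Pglyrp1, Saa2 and Hp, which did not pass, were above background on 1. Like Lcn2, these genes entered the test through the PBS arrays only, which favours falls. Without Anakinra 3, 3 of 17 tested members fell, and with the slide as a block 2 of 16 did, Lcn2 not among them (adjusted p = 0.0527). The list median was -0.61 (camera adjusted p = 2.60e-08), and the call was lost with an estimated correlation (adjusted p = 0.115). With 1 sample left out the median ran from -1.05, without Anakinra 2, to -0.52.

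Suprabasal differentiation genes shifted up as a list. Of 29 tested, 14 rose, 0 fell and 15 did not pass, with a list median of 0.70 (camera adjusted p = 2.77e-21; 0.0340 with an estimated correlation); adjusted over the list alone 25 rose. The desmosomal cadherins Dsg1a and Dsc1 rose at 1.78 ± 0.15 and 1.23 ± 0.11, the cross-linking enzyme Tgm1 at 0.71 ± 0.07 and filaggrin, Flg, at 0.83 ± 0.12. Loricrin, Lor, was at 0.73 ± 0.15 (adjusted p = 0.0960). Of 17 basal keratinocyte genes none passed, with a median of 0.09 (camera adjusted p = 0.234) and Krt15 at 0.52 ± 0.19. None of the 16 stress and simple-epithelial keratin and Sprr genes passed (median 0.19, adjusted p = 0.423), although adjusted over the list alone 5 rose and 3 fell; Krt8 was at -0.43 ± 0.21, Krt18 at -0.47 ± 0.13, Sprr3 at 0.81 ± 0.13 and Sprr2d at -0.69 ± 0.12. Without Anakinra 2 the count of suprabasal genes that rose was 8, without Anakinra 3 it was 9, and with the slide as a block it was 0, while the list's shift stayed past the threshold in each case.

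Interferon-stimulated genes were lower as a list, with a median of -0.52 (camera adjusted p = 1.06e-08), a call lost with an estimated correlation (adjusted p = 0.280). Of 26 tested, 4 fell, 0 rose and 22 did not pass, and adjusted over the list alone 11 fell; without Anakinra 3 the number that fell was 2. The immunoproteasome subunit gene Psmb8 fell at -1.28 ± 0.09, the antiviral membrane protein gene Bst2 at -0.73 ± 0.07 and Oasl2 at -1.33 ± 0.17. The other that fell, Isg15 at -1.01 ± 0.14, has a probe that the array design places on chromosome 17, which is not the gene's, so it may measure another gene; without it, a step chosen after its value was seen, the list median was -0.48. With the slide as a block none of the 4 passed (adjusted p = 0.0503 for Psmb8, 0.0756 for Bst2, 0.122 for Oasl2 and 0.123 for Isg15), and with quantile scaling Oasl2 did not (adjusted p = 0.0725). Cell cycle genes had no member past the threshold among 26, also adjusted over the list alone, and a small list shift with a median of -0.15 (camera adjusted p = 1.39e-05; adjusted p = 0.140 with an estimated correlation); Mcm6 was at -0.32 ± 0.06 and Aurkb at -0.34 ± 0.07. Among 18 sterol biosynthesis genes none passed, with a median of 0.18 (camera adjusted p = 3.78e-05; adjusted p = 0.131 with an estimated correlation), and 4 rose adjusted over the list alone; Cyp51 was at 0.37 ± 0.06 and Insig1 at 0.36 ± 0.07.

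Of 19 EGFR ligand and ras-MAPK output genes, 1 rose, the ligand epigen (Epgn) at 0.87 ± 0.10, and 18 did not pass; without Anakinra 2, without Anakinra 3 and with the slide as a block (adjusted p = 0.0503) 0 rose. The list's median was -0.08 while its mean was 0.01, and the test, which pointed down, did not pass (adjusted p = 0.764); adjusted over the list alone 3 rose and 3 fell. Of 20 protease and matrix genes, 18 did not pass. The stromelysin gene Mmp3 fell at -1.56 ± 0.07 and its inhibitor Timp1 rose at 0.55 ± 0.06. The list median was -0.05 (camera adjusted p = 0.980), and adjusted over the list alone 6 rose and 4 fell. With the slide as a block Timp1 did not pass (limma adjusted p = 0.0753). Without Anakinra 3, 0 of the 20 rose and 2 fell. None of 13 oxidative stress genes passed, where the median was 0.02, the mean -0.05 and the test pointed down (adjusted p = 0.828), with Gsr at -0.49 ± 0.08 and Srxn1 at 0.26 ± 0.06; adjusted over the list alone 1 rose and 3 fell. None of 14 heat shock and early response genes passed, also adjusted over the list alone (median -0.03, adjusted p = 0.444), with Atf3 at -0.34 ± 0.07 and Jun at 0.24 ± 0.06.

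Markers of other cells that a newborn epidermal preparation can hold were measured as well. Of 17 fibroblast markers, 2 rose, the matrix proteoglycan Lum at 1.43 ± 0.15 (adjusted p = 0.0200) and the collagen Col3a1 at 0.95 ± 0.13 (adjusted p = 0.0402), and 15 did not pass. The abundant collagens Col1a1 and Col1a2 were at 0.23 ± 0.14 and 0.18 ± 0.10, and Dcn was at -0.38 ± 0.07. The fibroblast list had a median of 0.33 (camera adjusted p = 2.82e-05; adjusted p = 0.325 with an estimated correlation), and adjusted over the list alone 5 rose and 1 fell. All 10 melanocyte markers had a positive sign and none passed, with a median of 0.24 (camera adjusted p = 0.000384; adjusted p = 0.325 with an estimated correlation), Kit at 0.41 ± 0.09 and Ednrb at 0.52 ± 0.12; adjusted over the list alone 2 rose. Of 11 hair follicle markers 1 rose, Krt79, a keratin of the follicle opening, at 0.86 ± 0.06, also adjusted over the list alone (list median 0.09, adjusted p = 0.184). None of 9 immune cell markers passed, also adjusted over the list alone (median -0.08, adjusted p = 0.444), with Csf1r at -0.33 ± 0.11 and Thy1, also on the fibroblast list, at 0.40 ± 0.14. None of 5 endothelial markers passed, also adjusted over the list alone (median -0.18, adjusted p = 0.287), with Egfl7 at -0.26 ± 0.08 and Kdr at -0.45 ± 0.15, above background on 1 of the 3 Anakinra arrays. Without Anakinra 2, the fibroblast list had 1 gene that rose, and without Anakinra 3 it had 0. With the slide as a block it had 0 as well (adjusted p = 0.0555 for Lum and 0.142 for Col3a1). Lum did not pass with quantile scaling (adjusted p = 0.382) and was at 0.51 with normexp background correction.

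**Figure D2:**
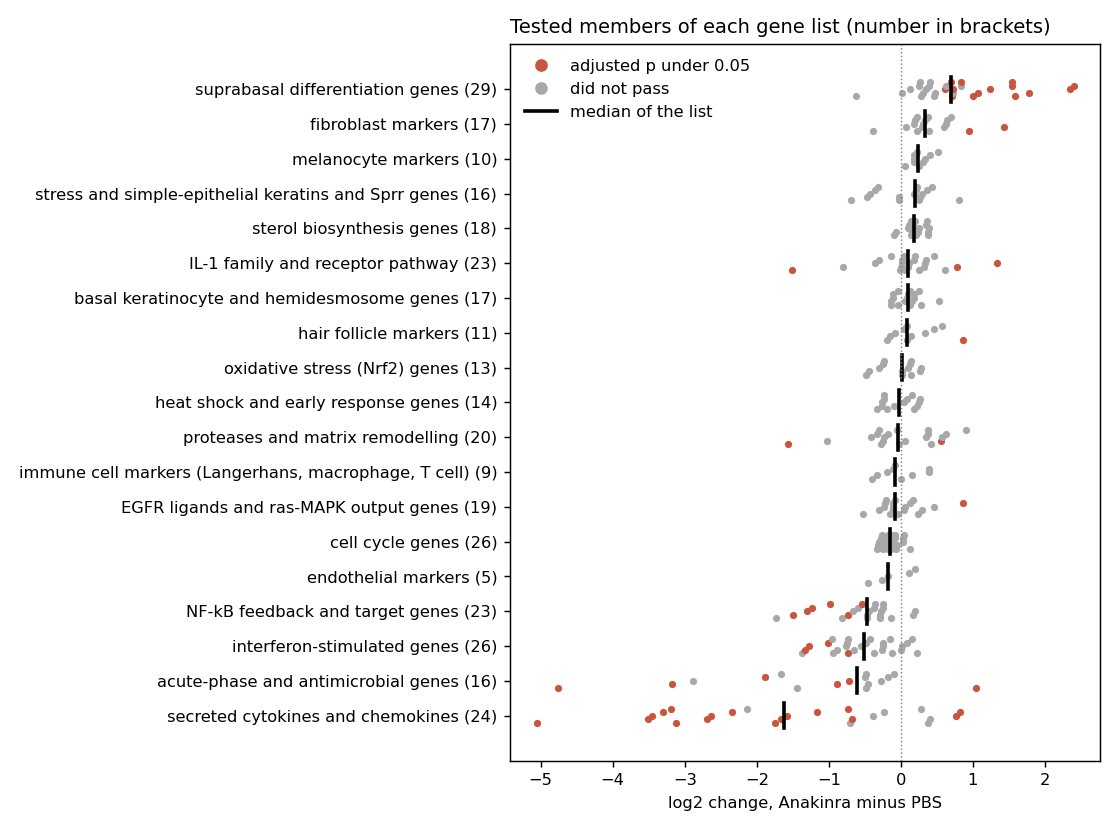
Log2 change of every tested member of the 19 gene lists, Anakinra minus PBS; each point is a gene, red where the adjusted p is under 0.05, and the black line is the list's median. Secreted cytokines and chemokines lie lowest with a median of -1.62, and suprabasal differentiation genes highest with 0.70.

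The 6 arrays lay on 2 slides, each scanned separately, with PBS 2, PBS 3 and Anakinra 1 on slide 1 and PBS 1, Anakinra 2 and Anakinra 3 on slide 2. Cxcl5 differed by -5.03 within slide 1 and -4.84 within slide 2, Ccl20 by -3.45 and -3.50, Il1a by -1.41 and -1.55, Nfkbia by -1.15 and -1.37, and Krt1 by 2.39 and 2.24. With the slide as a block, 18 genes were higher and 35 lower, and within either slide, where 1 group had a single array, limma called 0. Of the 47 called genes that the fixed rule named, 23 stayed past the threshold with that block. In the blocked fit Cxcl5 (adjusted p = 0.0233), Ccl20 (adjusted p = 0.0130), Il1a (adjusted p = 0.0297) and Nfkbia (adjusted p = 0.0444) stayed past the threshold, and Krt1 (adjusted p = 0.0599) and Krt10 (adjusted p = 0.0938) did not. The list medians in that fit were -1.58 for cytokines (camera adjusted p = 2.15e-14), -0.44 for NF-kB genes (adjusted p = 5.53e-13), -0.79 for acute-phase genes (adjusted p = 9.78e-08), 0.69 for suprabasal genes (adjusted p = 3.28e-21), -0.64 for interferon-stimulated genes (adjusted p = 3.22e-09), -0.17 for cell cycle genes (adjusted p = 3.65e-05), 0.21 for sterol genes (adjusted p = 9.02e-06), 0.28 for fibroblast markers (adjusted p = 8.50e-05) and 0.21 for melanocyte markers (adjusted p = 0.000744). These used the preset correlation; without the block, an estimated correlation removed the calls for all but the cytokine, NF-kB and suprabasal lists. Within slides 1 and 2 the medians were -1.52 and -1.58 for cytokines, -0.52 and -0.39 for NF-kB genes, -0.99 and -0.53 for acute-phase genes, 0.69 and 0.60 for suprabasal genes, and -0.73 and -0.53 for interferon-stimulated genes. They were -0.10 and -0.19 for cell cycle genes and 0.25 and 0.20 for sterol genes. For fibroblast markers they were 0.26 and 0.34, and for melanocyte markers 0.25 and 0.15.

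The counts of called genes moved when 1 sample was left out. The effect of a given sample and that of having fewer samples were not separated. Without PBS 1, 1 gene was higher and 20 lower; without PBS 2, 1 and 7; without PBS 3, 30 and 34; without Anakinra 1, 43 and 41; without Anakinra 2, 97 and 137; and without Anakinra 3, 71 and 57. Of the same 47 named genes, 14 stayed past the threshold without PBS 1, 7 without PBS 2, 26 without PBS 3, 27 without Anakinra 1, 40 without Anakinra 2 and 36 without Anakinra 3.

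**Figure D3:**
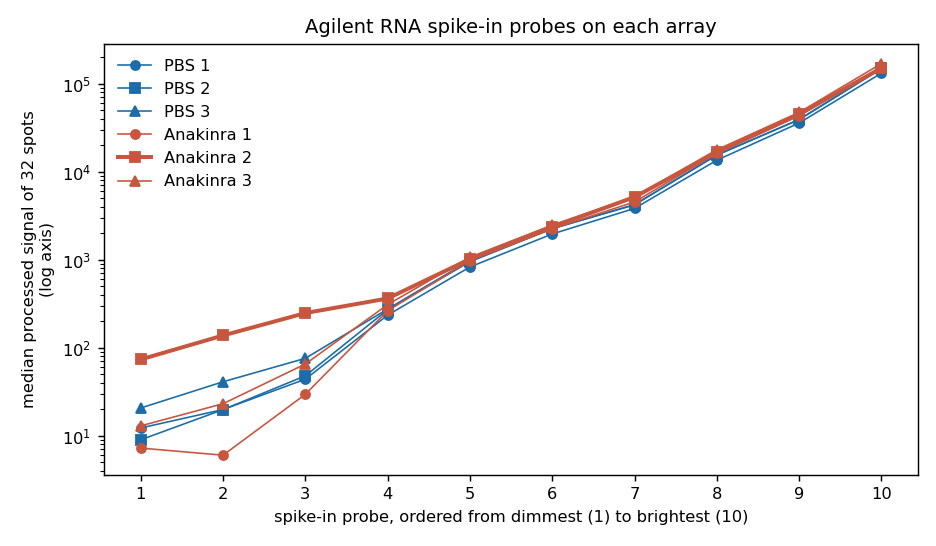
Median processed signal of 32 spots for each of 10 Agilent RNA spike-in probes, from dimmest (1) to brightest (10), on a log axis; each line is an array, blue for PBS and red for Anakinra, with Anakinra 2 drawn thicker. The dimmest probe reads 73.4 on Anakinra 2 and at most 20.6 on the other arrays.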

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

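The test on background subtraction was written before its value was seen, and the other tests on the dim end of Anakinra 2 were chosen after its pattern was seen. The spike-in probes were not part of any comparison. The third dimmest of the 10 read 247 on Anakinra 2, above the highest PBS value of 75.5, which is why it is listed here. Signal from dim probes in general was higher on this array, with 86.5% of probes well above background. The treatment as the cause is argued against by the other 2 Anakinra arrays, where at most 56.1% of probes were well above background, less than on every PBS array. A smaller background subtraction is argued against too, since before any subtraction the 3 dimmest spike-ins, less the array's own negative controls, were at least 2.92 times their highest value elsewhere. Extra non-specific signal on that array may explain it, since the 3 dimmest spike-ins were at least 3.27 times as bright as on any other array while the 6 brightest were at 0.891 to 0.991 of the highest other array. The negative controls, at 80.6, were above the 67.7 and 70.9 of the other arrays on the same slide and within the 78.7 to 85.8 of the other slide, so the kind of signal stays open.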

How the results depend on the processing

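Of the 47 called named genes, 549 of 680 comparisons with another setting and 150 of 282 with a sample left out were past the threshold. No direction turned, but leaving out a sample or adding a block could not turn one, as the groups of these genes do not overlap. The medians of the cytokine, NF-kB and suprabasal lists kept their direction and stayed past the threshold under every setting run, between -1.95 and -0.54, -0.80 and -0.35, and 0.37 and 0.76. Counts of called genes moved most. Apart from the stricter thresholds, which can only lower the counts, the cause was not tested. Genes higher and lower numbered 8 and 49 with median scaling, where the median change of all genes was -0.32 against 0.013 as reported. Without a background filter they were 7 and 29, of 27573 tested. With only genes above background on all 6 arrays they were 338 and 240, of 14132. With trend and robust variance they were 411 and 375, of which 274 were among the 292. With the slide as a block they were 18 and 35, of which 51 were among the 292. They were 19 and 38 at an adjusted p under 0.01, 65 and 59 at 2-fold or more, and, both added after seeing the data, 243 and 207 with cyclic loess and 368 and 400 in the brighter part of the genes. Leaving out 1 sample gave 1 to 97 higher and 7 to 137 lower genes, with the fewest without PBS 1 or PBS 2. Other settings stayed within 1.5 times of the counts in the report.

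The replicate block gave 0 genes higher and 0 lower (limma; 2653 genes had an unadjusted p under 0.05 without it), with Il1a at -1.51 (adjusted p = 0.176). Same-numbered samples deviated with correlations of 0.41, -0.49 and -0.21, and not every sample correlated best with its own number. The labels do not state whether same-numbered samples share a preparation. With 3 samples per group and brighter dim probes on Anakinra 2, these correlations cannot decide it.

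With an estimated correlation the camera calls were lost, at unchanged medians, for acute-phase genes (-0.61), interferon-stimulated genes (-0.52), cell cycle genes (-0.15), sterol genes (0.18), fibroblast markers (0.33) and melanocyte markers (0.24). With fry, fibroblast (0.33) and melanocyte markers (0.24) were lost and hair follicle markers (0.090) passed. Median scaling turned the medians of lists and genes that lay near 0, relative to its shift of all genes: IL-1 family -0.23, basal -0.24, stress keratins -0.14, sterol -0.15, oxidative stress -0.31, melanocyte -0.094 and hair follicle -0.24, and Il1r1 -0.085, Il1rap -0.23, Srxn1 -0.066, Jun -0.085 and Ptgs2 -0.13. Of these only the sterol and melanocyte lists had passed before, and neither passed then. The following other turns were all of values that did not pass in either setting. The endothelial list was at 0.091 with normexp and 0.20 without a filter, where the immune list was at 0.15. The protease list was at 0.012 in the authors' table and 0.17 with every probe on its own, and the heat shock list was at 0.028 in the authors' table and 0.017 with cyclic loess. Hras was at 0.013 with quantile scaling, 0.0053 in the authors' table and 0.028 with cyclic loess, Il1b at 0.060 with normexp, and Il1rap at -0.011 with the mean of the probes and -0.067 with every probe on its own. The basal list passed with quantile scaling (0.14), cyclic loess (0.14) and in the brighter genes (0.094), where the IL-1 family list (0.076) and Il1rn (-0.36) passed too, and the stress keratin list passed with quantile scaling (0.19).

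With 1 sample left out, Il1a ran from -1.57 to -1.46 and passed except without PBS 1 or PBS 2. The basal list ran from 0.029 to 0.14, passing without PBS 1 or Anakinra 2, and the IL-1 family list from 0.073 to 0.15, passing without Anakinra 2. The endothelial list ran from -0.57, where it passed without Anakinra 2, to 0.24. Values on both sides of 0, none of which passed, ran from -0.072 to 0.037 for the protease list, -0.90 to 0.44 for Il1b, -0.11 to 0.26 for Il1rap and -0.11 to 0.038 for Hras. The cause was not tested. Signal over background limits Il1b, Lcn2, Csf3 and Cxcl2, since each was below background on at least 1 Anakinra array.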

Other observations

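The genes in this part were chosen after their values were seen, and so were the test for a single culture and the splits of the samples. The tests on dim probes, on ATF4 target genes and on related neighbours were written before their values were seen. Some genes outside the lists that share a function or a family changed; members of the same families that did not change were not counted. Cyp7b1, which acts on the 25-hydroxycholesterol that Ch25h makes, fell at -2.22 ± 0.22 (adjusted p = 0.0170; above background on 2 of 3 Anakinra arrays; from -2.66 to -1.04 in 6 alternatives, past the threshold in 4), alongside Ch25h at -2.15 ± 0.06 (adjusted p = 0.000697). Gsdmc, Gsdmc2 and Gsdmc3, neighbouring gasdermin genes, rose at 2.04 ± 0.14, 1.74 ± 0.17 and 1.23 ± 0.10, whereas Gsdmd, the pore-forming gasdermin of inflammasome-driven cell death, fell at -0.88 ± 0.10. The protease inhibitor genes Serpinb12 and Serpinb11 rose at 1.15 ± 0.13 and 0.81 ± 0.09. The bacterial sensors Nod2 and Tlr2 fell at -1.95 ± 0.08 and -1.06 ± 0.10, the death receptor gene Fas at -0.95 ± 0.11, and the metal-binding Mt2 and Mt1 at -0.88 ± 0.07 and -0.56 ± 0.07, with the zinc importer Slc39a4 at -1.23 ± 0.18. Each of these genes kept its sign under all 5 other scalings or background corrections. With the slide as a block Ch25h (adjusted p = 0.0130), Nod2 (adjusted p = 0.0233) and Gsdmc (adjusted p = 0.0498) stayed past the threshold and the others named here did not. Of the 6 alternatives, which include that block, Ch25h, Nod2 and Gsdmc passed in 6, Mt1 in 3 and the others in 4. The calls of the others were therefore also lost under some scaling or background correction.

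Some genes of amino acid metabolism and uptake, chosen after their values were seen, fell in small steps: the serine hydroxymethyltransferase Shmt2 at -0.57 ± 0.09, the proline enzyme Pycr1 at -0.67 ± 0.09, Pck2 at -0.55 ± 0.06 and the transporters Slc1a5 at -0.54 ± 0.08 and Slc7a3 at -0.99 ± 0.12, together with the stress cytokine Gdf15 at -1.05 ± 0.13. With the slide as a block none of the 6 passed (adjusted p between 0.0759 and 0.154), and amino acid genes as a whole were not tested. Many of these are targets of ATF4, the transcription factor of the amino acid stress response, so a hypothesis is that its output may be lower under Anakinra. A list of 30 other ATF4 targets, without these genes and without members of the fixed lists, was tested. Atf4 itself was counted among its members. All 29 tested members had a negative sign and none passed singly. Their median was -0.29 (camera p = 5.20e-12, and 0.0479 with an estimated correlation, neither adjusted over lists). With an estimated correlation the cell cycle list had an unadjusted camera p of 0.0444. It did not pass once adjusted (adjusted p = 0.140). The median of the ATF4 list was lower than in each of 10000 random lists matched on mean signal. That is a share of 1e-04, the smallest that number can give. Genes of this brightness were lower in general, as the random lists had a median of -0.08, their middle 95% running from -0.13 to -0.0048, so part of the shift is shared with them. Relative to the median of all genes, which leaves that part in, the list stayed between -0.36 and -0.22 under every scaling tried, while 26 of the 29 were negative with quantile or cyclic loess scaling and 27 in the authors' value table. Cth had the smallest p at -0.80 ± 0.13 and Atf4 itself was at -0.22 ± 0.10. The shift has the direction that the hypothesis predicts. It was measured on the same arrays that gave the hypothesis, so it is not independent support. The random lists drew genes singly and do not allow for correlation among ATF4 targets. Lower demand on the pathway and lower Atf4 transcript cannot be separated with these values.

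Interferon-stimulated genes were lower in Anakinra by a median of -0.52. A difference between arrays shared by dim probes in general is argued against, since none of 10000 random lists matched on mean signal had a median as low. That is a share of 1e-04, the smallest that number can give, and their middle 95% ran from -0.05 to 0.17. The random lists drew genes singly and do not allow for correlation among interferon-stimulated genes, so the share is likely too small. A single culture as the cause is argued against by leaving out each sample in turn, where the median nearest to 0 was -0.41. An effect of the treatment stays open as a hypothesis, and with an estimated correlation the list's adjusted p of 0.280 did not pass.

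Called genes lay next to each other more often than chance. Among 14080 tested genes placed in order on the GRCm38.p6 assembly, 21 neighbouring pairs were called in the same direction, against a mean of 2.74 in 10000 permutations of the calls (permutation p = 0.0001, the smallest they can give). Cross-hybridisation between related genes could produce such pairs, and 12 of the 21 joined genes of similar symbol, such as Cxcl1 and Cxcl2 or Mt1 and Mt2. Without these, 9 pairs were left against a mean of 2.58 (permutation p = 0.0011), which argues against it as the whole cause, although Flg and Hrnr in that set are related in sequence. The others included Fas with Ch25h, Csf2 with P4ha2, Cxcl16 with Zmynd15, Tmem98 with Ccl2, and Exoc3l4 with Tnfaip2, all lower. A shared regulatory region is a hypothesis that was not tested here.

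The real grouping of the 6 samples gave 292 called genes and the highest of the other splits gave 1. With 10 splits, the real one included, the share reaching the real count cannot be less than 1 in 10, so 6 samples are too few to exclude by this that the split arose by chance.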
